A study of Mus musculus with 7 samples.

How the data were processed

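RNA of sorted tdTomato-positive tumour cells from adult C57BL/6 mice with glioblastoma was measured in 7 libraries, 3 WT and 4 Fyn-KO. Per the labels, the cells were lysed, RNA was purified on columns, and libraries were made with the Lexogen QuantSeq 3' mRNA-seq kit. Per the submitters' processing notes, reads were aligned with Bowtie2 to mm10 (GRCm38), bedtools was used, and DESeq2 1.32.0 was run. The annotation, the strand of counting and the versions of Bowtie2 and bedtools are not given in the sources used here.

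The deposited table holds 1 count per gene and library, and the values are whole numbers, read here as counts of tags without molecular identifiers. The authors call it modified, and what was modified is not given in the sources used here. It has 23282 entries with 23236 distinct symbols. For 46 entries an earlier symbol is repeated, and each was kept as its own gene. Another 27 carry dates in place of symbols, and 6683 have no count in any library. Of the symbols, 22171 are in GENCODE M21 for GRCm38 and 23124 are in that annotation, in RefSeq or among synonyms. Coordinates are from GENCODE M21. Each column was joined to a group, and all but 1 to a sample by its label. The exception is the column of WT replicate 3. The description of 1 WT sample names that column, but the column's name is also the title of another WT sample. It was therefore used as a WT library without a sample of its own. Replicate numbers here follow the columns and are not used to pair libraries.

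Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (at least 10 counts in enough libraries and 15 in all), which left 13122 genes, and libraries were scaled by TMM factors. Fyn-KO was compared with WT by the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and the log2 fold change as Fyn-KO minus WT. Its p-values rest on the spread between these libraries, with 1 spread per gene fitted to both groups. The WT libraries differed more from each other than the Fyn-KO libraries did. CPM are counts per 1000000 counts of the library total. Values are given as mean ± SD over libraries. Log2 fold changes are given with an approximate SE, the absolute log2 fold change over the square root of its F value. Single values were compared by an exact two-sided permutation test over the 35 splits of 7 libraries into 3 and 4, whose smallest p is 0.0286.

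A fold against a group in which each library has no count was computed against a floor of 3 counts per library (0.252 CPM for WT and 0.334 CPM for Fyn-KO) and is given as a lower bound. The fitted log2 fold change of such a gene is not a measured size, since the counts set only this bound. With 1 to 3 counts in a group the ratio of pooled counts is given with its 95% exact interval. These floors and intervals cover counting error only. Depth was 8976745 to 16371244 counts per library. Tags of near-identical genes, such as H2-K1 and H2-D1, Hba-a1 and Hba-a2, the Hsd3b family and ribosomal protein pseudogenes, can be assigned to either.

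The gene lists numbered 54, namely 31 of pathways, 5 of tumour states, 14 of cell types and 4 of sample quality. The 47 lists with 5 or more tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the lists. A list's level in a library is the mean log2 of CPM plus 1 over its members with a count. Genes named in the text are Fyn and the measured members of its family, and the 10 genes with the largest log2 fold change in each direction. These 10 had to pass the threshold, not overlap between the groups in CPM and reach a mean of 10 CPM, and predicted genes were left out. Up to 4 members by p of each list called by camera and of each cell type list were also eligible, and up to 3 members past the threshold of each other list. From these the text names examples of each list, chiefly genes whose call did not change when 1 library was left out, a selection made after the values were seen. Some genes that the rule takes and 1 list are not reported here. The test, the lists, the rule for named genes and the alternatives were set before the data were examined, except where stated.

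A further 11 lists were written during the analysis, for steroid hormone synthesis, ovarian granulosa and luteal cells, adrenal cortex, adrenal medulla, testis Leydig cells, testis Sertoli cells, oocytes, placenta trophoblast, Hox genes of paralog groups 5 to 13, lung epithelium and liver. The lists of Hox genes and placenta were written before the values of their genes were looked at, those of oocytes and Sertoli cells before the values of most, and the others after. Genes of these lists are named as measured values outside the rule. The list of mitochondrially encoded genes could not be used, since the table holds none of its 15 members.

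Alternatives were RLE factors, library sizes alone, no filter, a minimum count of 50, DESeq2 1.42.0, limma-voom with quality weights, robust edgeR, a block for the replicate number, an adjusted p under 0.1, each library left out in turn, an estimated correlation in camera, fry, pseudocounts of 0.1 and 5, TMM-scaled CPM for the list levels, and all tested genes in the principal components. After the data were seen, 3 were added, leaving out Rn45s, testing only genes with 10 or more counts in at least 2 WT and 3 Fyn-KO libraries, and thinning each library to the smallest total. A block for sex was not fitted. The fit was tested on simulated data with 13122 genes and the same fitted spread per gene in both groups. It recovered 0 of 66 genes changed 4-fold, 14 of 67 changed 64-fold and 31 of 67 changed 256-fold, with 1 false call. In the data, Pearson correlations of log2 CPM were 0.460 to 0.527 between WT libraries and 0.852 to 0.911 between Fyn-KO libraries. The simulation lacked this difference, so its false calls need not hold for these libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.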

Results

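Gene expression was measured by QuantSeq, a method that sequences tags from the 3' ends of polyadenylated RNA, in tumour cells of adult C57BL/6 mice with glioblastoma. Per the labels, the cells were sorted by flow cytometry for the red fluorescent protein tdTomato, and each mouse gave 1 library. The 7 libraries were 3 from mice with wild-type tumour cells (WT) and 4 from mice with Fyn-knockout tumour cells (Fyn-KO). Fyn encodes a non-receptor tyrosine kinase of the Src family. The WT libraries held 12775751, 16371244 and 11911864 counts, and the Fyn-KO libraries held 9385117, 10396507, 9135724 and 8976745. The 1 comparison that the labels name, Fyn-KO against WT, asks which transcripts differ in glioblastoma cells when Fyn is knocked out.

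The WT libraries held fewer genes than the Fyn-KO libraries although they held more counts. Genes with 1 or more counts numbered 7723, 9924 and 9704 in the WT libraries (9117 ± 1212, mean ± SD, n = 3) and 13899, 13762, 14548 and 13535 in the Fyn-KO libraries (13936 ± 435, n = 4). The difference of 4819 genes had an exact two-sided permutation p of 0.0286, the smallest that the 35 splits of 7 libraries into 3 and 4 allow. Total counts were higher in WT (13686286 ± 2365021 against 9473523 ± 637864, exact permutation p = 0.0286). Rn45s, a precursor of ribosomal RNA, took 2.32 ± 0.801% of the counts in WT and 12.2 ± 2.96% in Fyn-KO, and Malat1, a nuclear non-coding RNA, took 0.876 ± 0.239% and 2.29 ± 0.180%. The 10 most abundant genes together took 7.23 ± 1.34% and 18.6 ± 3.00%. Of the detected genes, 13.4 ± 8.22% in WT and 1.44 ± 0.210% in Fyn-KO had exactly 1 count. These shares each had an exact permutation p of 0.0286.

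**Figure D1:**
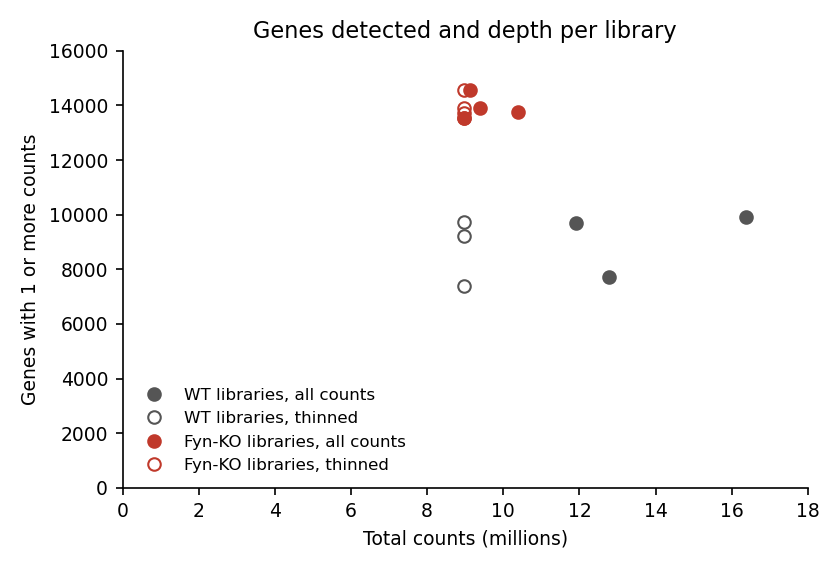
Genes with 1 or more counts (y axis) against total counts (x axis), for 3 WT and 4 Fyn-KO libraries, with all counts (filled points) and after thinning to 8976745 counts each (open points). With all counts the WT libraries lie between 7723 and 9924 genes and the Fyn-KO libraries between 13535 and 14548.

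Fyn itself was lower in the Fyn-KO libraries but was not absent from them. The gene (ENSMUSG00000019843.14, GRCm38 chromosome 10, 39368855 to 39565381, plus strand) stood at 1039, 719.9 and 1604 counts per 1000000 (CPM) in WT (1121 ± 448, mean ± SD, n = 3) and at 105, 106, 74.5 and 190 CPM in Fyn-KO (119 ± 49.5, n = 4). The WT mean was 9.43 times the Fyn-KO mean, with a log2 fold change of -3.43 ± 0.51 (SE) and a Benjamini-Hochberg adjusted p of 0.0121 in the edgeR quasi-likelihood test. The exact permutation p of the CPM was 0.0286. The altered part of the gene is not given in the sources used here, and 3' tags from outside it are counted whether or not a protein is made.

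Of the other Src family kinases, Frk and Yes1 rose. Frk (chromosome 10, 34483399 to 34611278) had no count in WT and stood at 20.4 ± 4.78 CPM in Fyn-KO, at least 81-fold higher. Yes1 had 1 count in all WT libraries together and 16 ± 10.8 CPM in Fyn-KO, a ratio of 657 with a 95% counting interval of 117 to 25977. In WT, 17.6% of genes at 100 CPM or more in 1 library lay under 1 CPM in another, so missed transcripts may add to these rises. Among genes with 10 or more counts in at least 2 WT and 3 Fyn-KO libraries, which leaves out Frk and Yes1, 3 family members were tested. There 0 rose and 1 fell, which was Fyn itself. Src did not pass the test at 71.2 ± 90.7 CPM in WT and 13.7 ± 4.88 CPM in Fyn-KO (adjusted p = 0.246). Without WT replicate 1 it did (log2 fold change -2.78, adjusted p = 0.0420). Lyn stood at 22.9 ± 21.9 and 27.3 ± 5.66 CPM (adjusted p = 0.949), with a log2 fold change of 0.23, and of -0.35 without WT replicate 1. Lck and Blk, kinases of lymphocytes, had no count in WT and 1.83 ± 3.52 and 0.666 ± 1.33 CPM in Fyn-KO, and Fgr had no count in any library. Among 6 tested members of the family list, which includes Fyn, 2 rose, 1 (Fyn) fell and 3 did not pass. The same counts held when adjusted over the list alone, and without WT replicate 1, 2 fell. The list's median log2 fold change was negative, its mean was 1.72, and camera did not call it (direction down, adjusted p = 0.599). Fry called it higher (adjusted p = 0.0473), and the list's level was 0.78 higher in Fyn-KO (exact permutation p = 0.0286, 0.0505 after adjustment over the lists). Of 21 tested substrates and partners of Fyn, 2 rose and 2 fell, against 4 and 5 when adjusted over the list alone. Without WT replicate 1, 3 rose and 5 fell, without WT replicate 2, 4 and 4, and without WT replicate 3, 5 and 4. That list's median was -0.05, its mean was 0.55, camera pointed down (adjusted p = 0.123) and fry pointed up (adjusted p = 0.319).

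Across the genome, 2493 genes were higher and 461 were lower in Fyn-KO among 13122 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Genes of steroid hormone synthesis and of steroid-producing tissues stood among the most abundant of the Fyn-KO libraries. Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, stood at 11984 ± 798 CPM in Fyn-KO and 49.5 ± 81.8 CPM in WT. Star, the carrier of cholesterol into mitochondria, stood at 4601 ± 439 and 12.5 ± 21.6 CPM, and Hsd3b1, the next enzyme of the pathway, at 6506 ± 1602 and 34.6 ± 60 CPM. Glial genes stood among those that fell. Olig2 and Sox10, transcription factors of the oligodendrocyte lineage, stood at 2671 ± 1087 and 2011 ± 241 CPM in WT and at 65.2 ± 64.2 and 58.6 ± 68.2 CPM in Fyn-KO, 41.0 and 34.3 times lower.

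Cyp11a1 (adjusted p = 0.0529), Star (0.0559) and Hsd3b1 (0.0998) did not pass the edgeR test with all libraries. WT replicate 3 held 144 CPM of Cyp11a1, 104 CPM of Hsd3b1 and 37.4 CPM of Star. Without it their adjusted p were 0.0101, 0.000747 and 3.26e-05, and without WT replicate 2 those of Cyp11a1 and Star were 0.0136 and 0.0484. Of 12 genes of steroid hormone synthesis, a list written after these genes had been seen, 5 rose, none fell and 7 did not pass, against 11 that rose when adjusted over the list alone. Without WT replicate 3, 10 of them rose. The list's median log2 fold change was 7.31, and also 7.31 with the genes at 0 in WT at their bound.

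The 10 largest increases that the rule for named genes took were led by Akr1cl, an aldo-keto reductase. Akr1cl had no count in WT and 2112 ± 372 CPM in Fyn-KO, at least 8385-fold higher. Its fitted log2 fold change was 17.56 (edgeR adjusted p = 0.000279), a size that the counts do not set. Mgarp, a mitochondrial protein of steroid-producing tissues, reached 1067 ± 208 CPM, at least 4236-fold higher. Sfrp4, a secreted Wnt inhibitor, reached 809 ± 156 CPM (at least 3213-fold higher), and Akr1b7, an aldo-keto reductase of the adrenal gland, 744 ± 92.2 CPM (at least 2956-fold higher). Smarca1, a chromatin remodeller, reached 588 ± 18 CPM, and Prss35, a secreted serine protease family member of the ovary, 549 ± 52.9 CPM, at least 2335-fold and 2181-fold higher. Mrap, the partner protein of the adrenocorticotropin receptor, Hoxc6, a homeobox gene of trunk positions, and Cst8, a cystatin, stood at 277 ± 21.3, 254 ± 17.4 and 249 ± 10.4 CPM, at least 1101-fold, 1008-fold and 989-fold higher. Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), had 3 counts in all WT libraries together and 1761 ± 205 CPM in Fyn-KO, a ratio of 24194 with a 95% counting interval of 8278 to 117321. Of the 2493 higher genes, 2340 (93.9%) had under 10 counts in each WT library and 1277 had none.

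**Figure D2:**
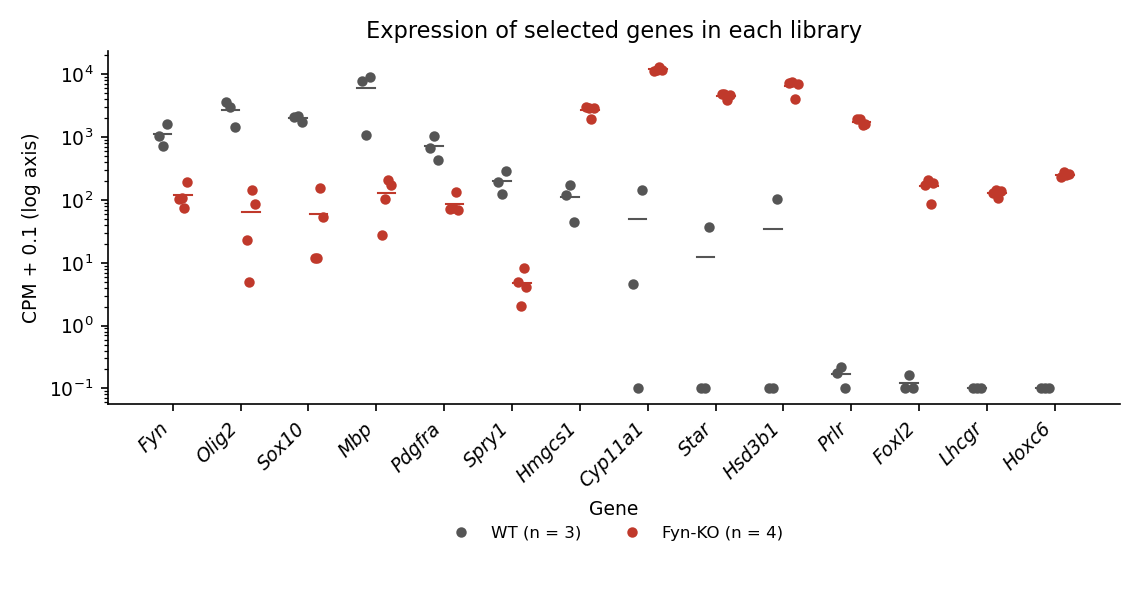
CPM of selected genes (x axis) on a log axis (y axis, 0.1 added to each value) in each of the 3 WT and 4 Fyn-KO libraries, with points for libraries and lines for group means. Fyn lies between 74.5 and 190 CPM in Fyn-KO and between 719.9 and 1604 CPM in WT.

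Among the 10 largest decreases, Alb, the serum albumin of liver, stood at 332 ± 81.8 CPM in WT and had no count in Fyn-KO, at least 992-fold lower. Its fitted log2 fold change was -14.94 (edgeR adjusted p = 0.00863), a size that the counts do not set. Chil3, a chitinase-like protein of lung macrophages, and Sftpa1, a lung surfactant protein, stood at 150 ± 128 and 120 ± 83.5 CPM and had no count in Fyn-KO, at least 447-fold and 359.6-fold lower. Scgb1a1, a secretoglobin of airway cells, stood at 85.9 ± 80.2 CPM and had 1 count in Fyn-KO, a WT over Fyn-KO ratio of 2935 (95% counting interval 526 to 115958). The source of these liver and lung transcripts in the WT libraries was not tested. Mmp12, a metalloproteinase of macrophages, stood at 165 ± 154 and 0.501 ± 1 CPM (log2 fold change -8.67). Acan, the proteoglycan aggrecan, fell from 122 ± 61.3 to 0.356 CPM (-8.47). Tmem163, a zinc transporter of neural cells, stood at 253 ± 219 and 0.712 CPM (-8.64), Tmem132b at 231 ± 117 and 2.35 ± 2.08 CPM (-6.80), and Astn1, a neuronal adhesion protein, at 152 ± 55.1 and 1.66 ± 1.91 CPM (-6.61). Some of these calls were close to the threshold and were lost when 1 library was left out, while the fold changes stayed large. Mmp12 did not pass without WT replicate 3 or Fyn-KO replicate 1, 2 or 3 (adjusted p 0.0518 to 0.0663, log2 fold change -7.21 to -8.25), nor did Acan without Fyn-KO replicate 1, 2 or 4 (0.0539 to 0.0561, -8.05 to -8.08). Tmem163 did not pass without WT replicate 3 or Fyn-KO replicate 4 (0.0540 and 0.0539, -7.48 and -8.29), nor did Astn1 without WT replicate 3 or any 1 Fyn-KO replicate (0.0555 to 0.0916, -6.07 to -7.15).

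The fitted log2 fold changes had a median of 8.83 among the higher genes, -2.88 among the lower genes and 0.45 among all tested genes. The counts do not set the fitted size of the 1277 higher genes without a WT count. Only 4 lower genes had under 10 counts in all 4 Fyn-KO libraries, so the medians of higher and lower genes are not comparable sizes. WT and Fyn-KO libraries did not overlap in CPM for 4909 genes (37.4% of those tested, where chance gives 5.71%). The counts moved with single libraries. Without WT replicate 2, 4585 genes were higher and 839 lower, without WT replicate 1 or 3 the lower genes numbered 729 and 716, and without Fyn-KO replicate 1, 2 or 4 they numbered 251, 247 and 262. Among the 6446 genes with 10 or more counts in at least 2 WT and 3 Fyn-KO libraries, 52 were higher and 146 lower, and 49 and 146 of them were also called among all tested genes. Other fits gave 24 higher and 320 lower genes (limma-voom with quality weights), 188 and 135 (a block for the replicate number) and 3699 and 774 (DESeq2).

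**Figure D3:**
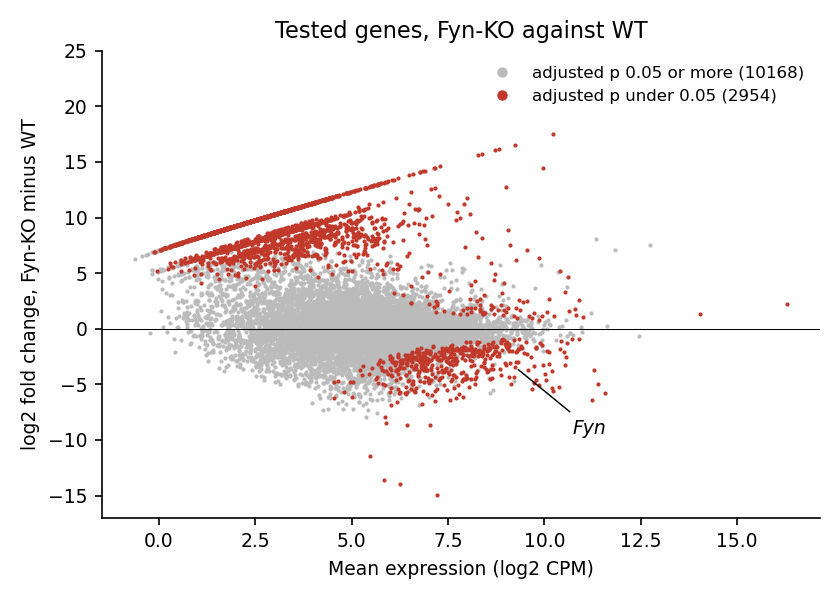
Fitted log2 fold change, Fyn-KO minus WT (y axis), against mean log2 CPM (x axis) for the 13122 tested genes. The 2493 higher and 461 lower genes are in red, and the straight upper edge is formed by genes without counts in WT.

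Oligodendrocyte progenitor and oligodendrocyte genes made up the gene group with the lowest camera p. Of 26 tested genes of the oligodendrocyte progenitor-like tumour state, none rose, 14 fell and 12 did not pass, against 22 that fell when adjusted over the list alone. Pdgfra, a growth factor receptor of progenitors, fell from 712 ± 310 to 86.9 ± 31.5 CPM (8.19 times lower, log2 fold change -3.00 ± 0.42), and Vcan, the proteoglycan versican, from 855 ± 361 to 156 ± 26.4 CPM (-2.45 ± 0.32). Lims2, an adaptor of integrin-linked kinase, fell from 438 ± 134 to 14.7 ± 7.6 CPM. The list's median log2 fold change was -4.55 (camera adjusted p = 1.13e-22 with the preset correlation, adjusted p = 0.162 with an estimated correlation). Its level, the mean log2 of CPM plus 1 over its members, was 7.81, 8.13 and 7.21 in WT and 2.34, 2.40, 5.19 and 4.13 in Fyn-KO. In the same libraries the level of the steroid synthesis list was 2.32, 2.40 and 2.37 in WT and 10.20, 10.26, 9.86 and 10.15 in Fyn-KO.

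Of 14 tested genes of mature oligodendrocytes, 6 fell and 8 did not pass, against 8 that fell when adjusted over the list alone. Mbp, a myelin protein, fell from 5993 ± 4269 to 128 ± 79.8 CPM (46.7 times lower), Cnp, a myelin enzyme, from 2069 ± 1414 to 91.5 ± 99.2 CPM, and Gjc3, a glial connexin, from 414 ± 279 to 8.55 ± 7.07 CPM. The list's median was -4.59 (camera adjusted p = 1.51e-07, adjusted p = 0.223 with an estimated correlation). Without WT replicate 3 or Fyn-KO replicate 4, 4 genes fell, and without WT replicate 2, 9. The steroid synthesis level was 2.36 ± 0.0410 in WT and 10.12 ± 0.177 in Fyn-KO.

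Some neural progenitor and stem cell genes fell, and most did not pass. Of 18 tested genes of the neural progenitor-like state, 5 fell and 13 did not pass, with the same count when adjusted over the list alone (median -1.68, camera adjusted p = 3.05e-07, adjusted p = 0.162 with an estimated correlation). Dll3, a Notch ligand, fell from 261 ± 84.8 to 5.5 ± 4.49 CPM, and Elavl3, an RNA-binding protein of neurons, from 363 ± 247 to 15.8 ± 13.4 CPM. The number that fell was 2 without WT replicate 3 or Fyn-KO replicate 2, and 3 without Fyn-KO replicate 1 or 4, and 1 gene rose without WT replicate 2. Of 15 tested neural stem cell genes, 1 rose, 4 fell and 10 did not pass, against 2 and 5 when adjusted over the list alone (median -2.71, camera adjusted p = 7.79e-05, adjusted p = 0.162 with an estimated correlation). Egfr, a growth factor receptor, fell from 178 ± 30.2 to 19.1 ± 8.24 CPM, and Notch1 from 223 ± 78.7 to 37.1 ± 10.8 CPM. Lfng, a modifier of Notch, rose from 3 counts in all WT libraries together to 9.49 CPM, a ratio of 129 (95% counting interval 43.9 to 630), and without WT replicate 3 or Fyn-KO replicate 4, 2 stem cell genes rose. Of 21 tested astrocyte-like genes, 2 rose, 4 fell and 15 did not pass, against 2 and 5 when adjusted over the list alone. S100b, a calcium-binding protein of glia, fell from 1788 ± 694 to 42.2 ± 35.8 CPM, Aldoc, an aldolase of astrocytes, from 349 ± 63.5 to 28.5 ± 4.96 CPM, and Fabp7, a fatty acid carrier of radial glia, from 606 ± 234 to 25.9 ± 23.6 CPM. The astrocyte-like list had a median of -0.03 and a mean of -1.05 (camera adjusted p = 0.00648, adjusted p = 0.162 with an estimated correlation). In the genes detected in both groups camera did not call it (adjusted p = 0.841), and its level did not separate the groups (exact permutation p = 0.314). The number of its genes that rose was 4 without WT replicate 2 or 3, 0 without Fyn-KO replicate 3 and 1 without any other library. Star stood at 4601 ± 439 CPM in the Fyn-KO and 12.5 ± 21.6 CPM in the WT libraries in which these groups were measured.

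Some ERK pathway genes fell, and most did not pass. Of 15 tested feedback and target genes of the ERK kinases, none rose, 4 fell and 11 did not pass, with the same count when adjusted over the list alone (median -1.67, camera adjusted p = 7.79e-05, adjusted p = 0.162 with an estimated correlation). Spry1, a feedback inhibitor, fell from 200 ± 79.8 to 4.71 ± 2.57 CPM (42.6 times lower), and Ccnd1, cyclin D1, from 2608 ± 1480 to 181 ± 119 CPM (14.4 times lower). Etv5, a transcription factor, fell from 169 ± 38 to 14.2 ± 10.2 CPM, and Phlda1 from 224 ± 145 to 17.2 ± 8.01 CPM. Without WT replicate 1, 7 genes fell. The list's level was 3.84 ± 0.597 in WT and 3.02 ± 0.342 in Fyn-KO (exact permutation p = 0.0857). Cyp11a1 stood at 11984 ± 798 CPM in the same Fyn-KO libraries and 49.5 ± 81.8 CPM in WT.

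The type I interferon, interferon gamma and MHC class I lists were lower in Fyn-KO by camera, but their levels did not separate the groups. The interferon gamma level was 7.50, 3.61 and 1.56 in WT and 3.47, 3.93, 3.30 and 4.10 in Fyn-KO (exact permutation p = 0.771), and the exact permutation p of the levels was 0.314 for type I interferon and 0.429 for MHC class I. Of 34 tested genes of the type I interferon response, 2 rose, 5 fell and 27 did not pass, with the same count when adjusted over the list alone (median -1.60, camera adjusted p = 5.96e-05, adjusted p = 0.223 with an estimated correlation). Ifit3 and Ifit1, antiviral proteins, fell from 572 ± 533 to 15.8 ± 7.42 CPM and from 288 ± 265 to 5.05 ± 3.53 CPM, and Sp100, a nuclear body protein, rose from no count to 3.83 ± 1.71 CPM, at least 15-fold higher. Of 30 tested interferon gamma response genes, 1 rose and 2 fell, against 0 and 2 when adjusted over the list alone (median -3.06, camera adjusted p = 0.000191, adjusted p = 0.704 with an estimated correlation). Gbp6, a guanylate-binding protein, fell from 205 ± 221 to 8.65 ± 4.64 CPM, and Tap1, the peptide transporter of antigen presentation, from 338 ± 343 to 24.5 ± 6.78 CPM. Of 19 tested genes of MHC class I presentation, 4 fell and 15 did not pass, against 4 that fell and 1 that rose when adjusted over the list alone (median -1.31, camera adjusted p = 0.000467, adjusted p = 0.567 with an estimated correlation). H2-K1 and H2-D1, heavy chains of MHC class I, fell from 2198 ± 2145 to 259 ± 67.1 CPM and from 1934 ± 1608 to 218 ± 81.7 CPM, with tags of these similar genes assigned as in the deposited table. The type I interferon list counted 3 falls without WT replicate 1, 11 without WT replicate 3 and 2 without any 1 Fyn-KO replicate, and 4 rises without WT replicate 2. The interferon gamma list counted 4 falls without WT replicate 2 and 12 without WT replicate 3, and the MHC class I list 9 without WT replicate 3. The interferon gamma list counted 2 rises without WT replicate 1 and 0 without Fyn-KO replicate 1 or 4, and the MHC class I list 1 rise without WT replicate 2 or 3 or Fyn-KO replicate 4. Without WT replicate 1 camera called neither the interferon gamma list (adjusted p = 0.891) nor the MHC class I list (0.0512), and among the genes detected in both groups it did not call the interferon gamma list (0.0606). Hsd3b1 stood at 6506 ± 1602 CPM in Fyn-KO and 34.6 ± 60 CPM in WT in these libraries.

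Nuclear-encoded genes of oxidative phosphorylation differed little. Of 54 tested, 1 rose, 4 fell and 49 did not pass, against 0 and 2 when adjusted over the list alone. Cox8a, a subunit of cytochrome oxidase, fell from 1374 ± 426 to 603 ± 87.1 CPM, and Ndufb3, a subunit of complex I, from 646 ± 24.7 to 217 ± 58.6 CPM. The list's median was -0.16 (camera adjusted p = 0.000123, adjusted p = 0.376 with an estimated correlation), while its level was 0.21 higher in Fyn-KO (exact permutation p = 0.343). In the genes detected in both groups camera pointed up (adjusted p = 0.841). With 1 library left out the number that fell ranged from 2, without Fyn-KO replicate 1, 2 or 4, to 7, without WT replicate 3. The number that rose was 2 without WT replicate 1 or 2, 5 without WT replicate 3 and 0 without Fyn-KO replicate 1, 2 or 4. Star stood at 4601 ± 439 CPM in Fyn-KO and 12.5 ± 21.6 CPM in WT.

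Glutamate receptor and synapse genes moved in both directions. Of 23 tested, 4 rose, 3 fell and 16 did not pass, against 5 and 6 when adjusted over the list alone. Nrxn2, a presynaptic adhesion protein, fell from 1796 ± 39.6 to 62.9 ± 44.6 CPM (28.6 times lower), and Grin2b, a glutamate receptor subunit, rose from no count to 12.6 ± 6.03 CPM, at least 50-fold higher. The median was -1.63 and the mean -0.12 (camera adjusted p = 0.0243, adjusted p = 0.567 with an estimated correlation), and the level did not separate the groups (exact permutation p = 0.429). Of 38 tested genes of G2/M and mitosis, none rose, 5 fell and 33 did not pass, against 3 that fell when adjusted over the list alone. Cdk1, the kinase of mitotic entry, fell from 442 ± 115 to 74.8 ± 29.8 CPM (5.91 times lower), and Plk1, a mitotic kinase, from 205 ± 73.7 to 37.5 ± 9.75 CPM (adjusted p = 0.0569 without Fyn-KO replicate 1). The G2/M list had a median of -0.90 (camera adjusted p = 0.0244, adjusted p = 0.658 with an estimated correlation) and a level 0.72 higher in Fyn-KO (exact permutation p = 0.314). Without WT replicate 2 camera called neither the synapse list (adjusted p = 0.123) nor the G2/M list (0.350), and 7 genes of the synapse list and 9 of the G2/M list rose. Without Fyn-KO replicate 3, 5 synapse genes fell, and 1 and 2 G2/M genes rose without WT replicate 1 and 3. Among the genes detected in both groups camera did not call the G2/M list (adjusted p = 0.260). Of the G2/M list 8 genes fell without WT replicate 1, and without Fyn-KO replicate 1, 2, 3 or 4 the numbers were 1, 2, 3 and 2. The steroid synthesis level was 2.36 ± 0.0410 in WT and 10.12 ± 0.177 in Fyn-KO.

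**Figure D4:**
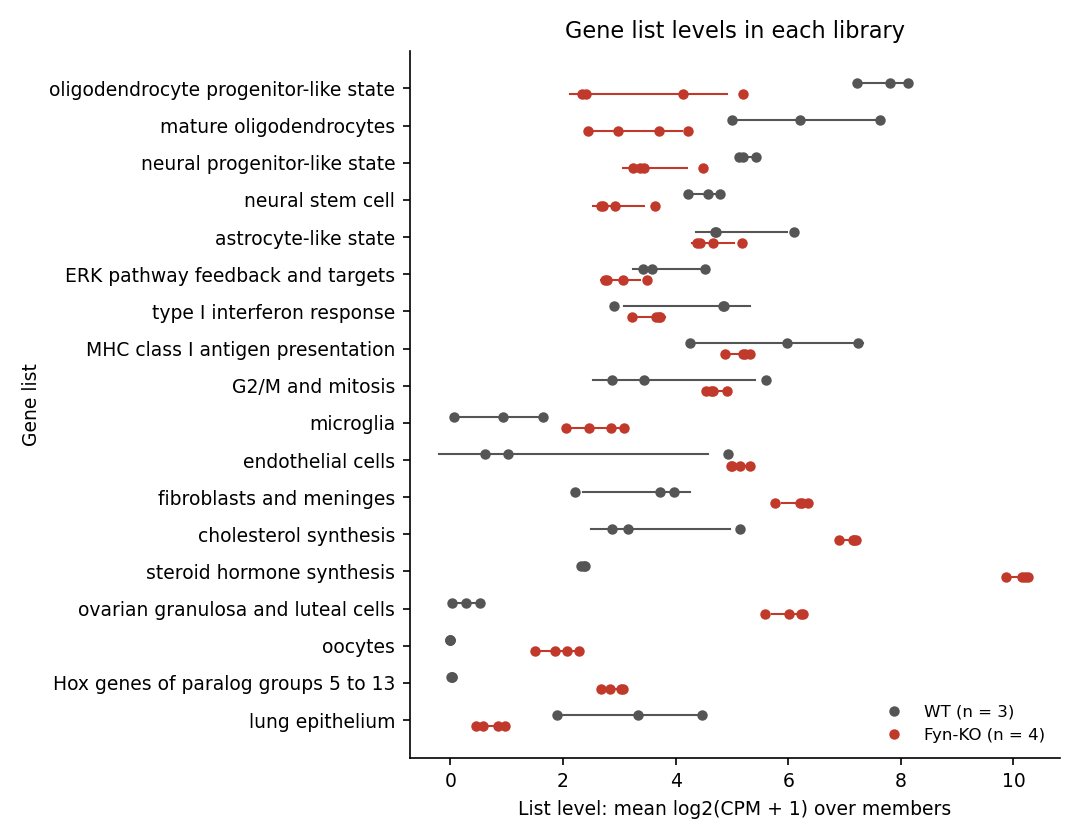
Level of selected gene lists (y axis) as the mean log2 of CPM plus 1 over the members (x axis) in the 3 WT and 4 Fyn-KO libraries, with points for libraries and lines for mean ± SD. The oligodendrocyte progenitor-like list lies between 7.21 and 8.13 in WT and between 2.34 and 5.19 in Fyn-KO.

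Cholesterol synthesis, TGF-beta and matrix genes held members that rose, although camera called 0 of the 47 tested lists higher (2 at an unadjusted p under 0.05, and 22 by fry). Of all 13122 tested genes 2493 were higher, and the shares of cholesterol synthesis and the mesenchymal-like state were no larger than that. Of 23 tested genes of cholesterol synthesis, 3 rose and 20 did not pass, with the same count when adjusted over the list alone (median 1.95, camera adjusted p = 0.0725). Without WT replicate 1, 2 or 3 the number that rose was 7, 9 and 5. Hmgcs1, an early enzyme of the pathway, rose from 112 ± 63.4 to 2707 ± 501 CPM (24.2 times higher, edgeR adjusted p = 0.00212), and Lss, which forms lanosterol, from 1 WT count to 77.3 ± 1.53 CPM, a ratio of 3171 (95% counting interval 569 to 125308). Of 20 tested TGF-beta targets, 8 rose and 1 fell, with the same count when adjusted over the list alone (median 2.96, and 2.87 with genes at 0 in WT at their bound, camera adjusted p = 0.0997). Without Fyn-KO replicate 1 or 4, 5 of them rose, and none fell without WT replicate 3 or any 1 Fyn-KO replicate. Ltbp1, a TGF-beta binding protein, rose from 3 WT counts to 176 ± 4.2 CPM (ratio 2412, 95% counting interval 825 to 11697), and Thbs1, thrombospondin 1, from no count to 76.5 ± 8.19 CPM, at least 304-fold higher. Extracellular matrix counted 10 higher and 3 lower of 44, the mesenchymal-like state 6 and 2 of 33, complement 7 and 0 of 16, and the hypoxia response 7 and 0 of 26. Without WT replicate 3 the higher genes numbered 17 for extracellular matrix, 12 for the mesenchymal-like state and 11 for the hypoxia response, and 2 complement genes fell. Without WT replicate 2, 12 hypoxia genes rose. Camera called cholesterol synthesis without WT replicate 1 (adjusted p = 0.0472) and called cholesterol synthesis, the hypoxia response (both 0.0281) and TGF-beta targets (0.00193) without WT replicate 3. Among the genes detected in both groups camera with the preset correlation called cholesterol synthesis higher (adjusted p = 1.01e-05). With an estimated correlation, run on all tested genes only, camera gave that list an adjusted p of 0.616. Cyp11a1 stood at 11984 ± 798 CPM in Fyn-KO and 49.5 ± 81.8 CPM in WT.

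Camera called none of the remaining pathway lists with all libraries. For comparison, 22.5% of all tested genes were called higher or lower. The higher and lower genes numbered 5 and 0 of 17 tested for NF-kB and inflammatory response, 3 and 1 of 17 for chemokines and cytokines, 0 and 1 of 6 for MHC class II and 2 and 2 of 11 for immune checkpoint ligands and immunosuppressive factors. NF-kB genes counted 1 rise without Fyn-KO replicate 1, 3 without Fyn-KO replicate 2 or 4, and 1 fall without WT replicate 1. The falls among chemokines and cytokines numbered 2 without WT replicate 1 or 2 and 3 without WT replicate 3. Of MHC class II, 2 genes fell without WT replicate 2, where camera called the list lower (adjusted p = 0.0197), none fell without any 1 of the other libraries, and 2 rose without WT replicate 1. Checkpoint genes counted 1 and 1 without Fyn-KO replicate 1 or 2, and 1 fall without Fyn-KO replicate 4.

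For G1/S they numbered 1 and 1 of 34, for p53 targets 1 and 0 of 21, for apoptosis regulators 5 and 1 of 24, for glycolysis 0 and 1 of 20 and for MYC targets 5 and 1 of 30. Cytosolic ribosomal proteins, some of which have near-identical pseudogenes, counted 8 and 0 of 76, with a median of 0.30 while camera pointed down (adjusted p = 0.203). Camera called that list lower without WT replicate 2 (adjusted p = 0.0255) and higher among the genes detected in both groups (4.54e-05). Without WT replicate 3, 20 ribosomal protein genes rose, against 2 without Fyn-KO replicate 1 and 3 without Fyn-KO replicate 2 or 4, and 1 fell without any 1 WT replicate. Camera called G1/S (adjusted p = 0.0158, 5 genes lower) and glycolysis (0.0457, 2 genes lower) lower without WT replicate 1. Without WT replicate 2, 9 genes each of the G1/S and p53 lists, 11 of the apoptosis list and 1 of the glycolysis list rose, and 1 p53 target fell. Without WT replicate 3, 3 glycolysis genes rose and 1 p53 target fell. Of G1/S, 2 genes rose without Fyn-KO replicate 4 and none fell without Fyn-KO replicate 1 or 2, no p53 target rose without Fyn-KO replicate 2, and no apoptosis gene fell without any 1 Fyn-KO replicate. MYC targets counted 8 rises without WT replicate 2, 2 without Fyn-KO replicate 1 and 3 without WT replicate 3 or Fyn-KO replicate 2, 3 or 4. Their falls numbered 3 without WT replicate 1 or 3, 2 without WT replicate 2 and 0 without any 1 Fyn-KO replicate.

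The unfolded protein and integrated stress response counted 4 and 1 of 27, glioma receptor tyrosine kinases and ligands 4 and 3 of 22, and integrins and focal adhesion 6 and 0 of 30. Wnt targets counted 3 and 1 of 13, the Notch pathway 4 and 2 of 17, and axon guidance 8 and 3 of 32. Without WT replicate 2 the rises numbered 7 for the unfolded protein response, 7 for glioma receptor tyrosine kinases, 10 for integrins and 5 for Wnt targets, and 3 integrin genes fell. The falls without WT replicate 1 numbered 3 for the unfolded protein response, 4 for integrins and 2 for Wnt targets, and 1 integrin gene fell without WT replicate 3. Without Fyn-KO replicate 1, 2 or 4, 2 genes of the unfolded protein response rose, and axon guidance counted 0 falls without Fyn-KO replicate 1 or 4 and 1 without Fyn-KO replicate 2 or 3. Of the lists that read sample quality, immediate early and dissociation genes counted 3 and 3 of 19, with 5 rises without WT replicate 2, 1 fall without Fyn-KO replicate 3 and none without Fyn-KO replicate 1, 2 or 4. Heat shock genes counted 5 and 1 of 17, and Hspd1, a mitochondrial chaperone, rose from 169 ± 74.7 to 1034 ± 129 CPM (6.13 times higher). Without Fyn-KO replicate 2, 3 heat shock genes rose. Camera did not call the heat shock list with all tested genes (adjusted p = 0.335) and called it higher among the genes detected in both groups (0.00598). Of the sex-linked list, Xist was the 1 gene tested, at 532, 0.855 and 269 CPM in WT and 548 to 599 CPM in Fyn-KO (adjusted p = 0.728), with tags of the overlapping Tsix not told apart here. None of the 15 mitochondrially encoded genes was in the table.

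Marker genes of other cell types were higher in Fyn-KO in several lists, and those of vessels and blood were also present in WT replicate 3. Set against 2493 higher of all 13122 tested genes, lists such as endothelial cells and monocytes and macrophages held no larger a share with all libraries. Of 9 tested microglia genes 4 rose. Cx3cr1, a chemokine receptor, rose from 1 WT count to 63.4 ± 12 CPM (ratio 2623, 95% counting interval 470.4 to 103653), and Fcrls to 23.1 ± 14.2 CPM (ratio 929.7, 166 to 36762). Of 16 endothelial genes 3 rose, among them Emcn, endomucin, from no count to 29.7 ± 20.5 CPM (at least 118-fold higher), and 12 rose without WT replicate 3. The endothelial level was 0.61, 1.03 and 4.94 in WT and 5.33, 5.15, 4.99 and 4.999 in Fyn-KO, and camera called the list without WT replicate 3 (adjusted p = 7.78e-05). Fibroblast and meningeal genes counted 4 higher and 1 lower of 12, with Dcn, decorin, at 0.996 ± 1.34 CPM in WT and 529 ± 53 CPM in Fyn-KO, and Lum, lumican, at least 327-fold higher. Pericyte and smooth muscle genes counted 3 and 1 of 11, with Myh11, smooth muscle myosin, at 0.168 and 103 ± 30 CPM. Without WT replicate 3, 6 of them rose, and without WT replicate 2, 2 fibroblast genes fell. Ependymal and choroid plexus genes counted 2 and 1 of 3, with Folr1, a folate receptor, at least 284-fold higher, and Enpp2, autotaxin, lower (492 ± 384 against 22.6 ± 7.36 CPM). Without Fyn-KO replicate 1 or 4, 1 of the ependymal genes rose. Pan-leukocyte genes counted 4 and 0 of 12, with 2 rises without Fyn-KO replicate 1 or 2 and 1 fall without WT replicate 2, and monocyte and macrophage genes 3 and 2 of 19, with Arg1, arginase, lower (158 ± 167 against 3.03 ± 0.638 CPM) and 7 higher without WT replicate 3. Entpd1, an ectonucleotidase, was at least 114-fold higher. Neutrophils counted 1 and 0 of 3, dendritic cells 0 and 1 of 3, T and NK cells 0 and 0 of 4, B cells 0 and 0 of 1, and neurons 0 and 1 of 8. T and NK cells counted 1 rise without WT replicate 2 or Fyn-KO replicate 1 or 4, B cells 1 without WT replicate 3, dendritic cells 1 without Fyn-KO replicate 4, and neurons 1 without WT replicate 1 or 3 and 2 without WT replicate 2. Of 8 erythroid genes none passed, and 7 rose without WT replicate 3, while 1 fell without WT replicate 1 or 3. Hba-a1, an alpha globin gene near-identical to Hba-a2, stood at 137 ± 165 and 726 ± 70.0 CPM (adjusted p = 0.174), and its log2 fold change was 4.29 (adjusted p = 0.00778) without WT replicate 3. Star stood at 4601 ± 439 CPM in Fyn-KO and 12.5 ± 21.6 CPM in WT.

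By camera with the preset correlation, 12 of the 47 tested lists were lower, 0 were higher and 35 were not called. Of the 35 splits of the libraries, 16 gave 12 or more called lists, with up to 15, so that the number of list calls was no larger than other groupings gave. With an estimated correlation none was called, and 7 had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance in 1 direction, called 22 lists higher and 5 lower. List levels could be computed for 53 lists, and 30 of them had the smallest possible exact permutation p of 0.0286. After Benjamini-Hochberg adjustment the smallest value was 0.0505, so that 0 lists passed. With 30 of 53 lists at the smallest p that 3 against 4 libraries allow, the adjustment could give no lower value.

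The Fyn-KO libraries resembled each other more than the WT libraries did. Across genes, Pearson correlations of log2 CPM were 0.852 to 0.911 between Fyn-KO libraries, 0.460 to 0.527 between WT libraries and 0.403 to 0.551 between the groups. Genes are not independent replicates. The first principal component of the 500 most variable genes held 78.2% of the variance and separated the groups.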

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

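The 3 patterns below were noticed in the data, and their tests were chosen after the results had been seen, except the count of Hox genes, whose prediction was written first.

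Steroidogenic genes were high and glial genes low in the Fyn-KO libraries. A candidate explanation is RNA or cells of a steroid-producing trunk tissue, added to the labelled cells despite the sort for tdTomato or in their place through a mix-up of samples, which was not tested and leaves the identity of the Fyn-KO libraries open, and 10 of 25 Hox genes of paralog groups 5 to 13 stood at 1 CPM or more in each Fyn-KO and under 1 CPM in each WT library, against a median of 3 and a 95th percentile of 6 in 10000 random lists of matched abundance. Cyp11a1, Hsd3b1 and Star, the most abundant such genes, stood at 11984, 6506 and 4601 CPM in Fyn-KO. The list of 12 steroid synthesis genes was written after their values were seen. Of them 12 reached 1 CPM in all 4 Fyn-KO libraries and 0 in all 3 WT libraries. However, 6 of the 12 were among the genes detected in both groups and 1 of those 6 was higher there. In each Fyn-KO library 16 of 18 ovarian, 5 of 10 oocyte and 3 of 8 adrenal cortex genes reached 1 CPM, against 0 of each in all 3 WT libraries. No Sertoli or placental gene did so. The ovarian and adrenal cortex lists were written after their values were seen, the oocyte list before most were. Transcripts missed by chance in WT may add to the pattern, but 3 genes at 1000 CPM or more in each Fyn-KO library (Akr1cl, Prlr and Star, of 41) lay under 1% of that in each WT library, where 2.47e-06 would be expected if WT libraries missed genes independently at the rate at which they missed each other's abundant genes (0.392%), and misses shared between libraries were not tested. Loss of Fyn in the tumour cells could also lower glial genes and remains open, since the steroidogenic genes were high in the same libraries and no value here separates them. The median share of the WT level that oligodendrocyte progenitor-like genes kept differed 16.1-fold between Fyn-KO libraries (0.802, 0.725, 11.7 and 3.66%). An effect of genotype alike in each library would not by itself give that spread, but it could act beside another cause. The shares cover 24 genes with a WT level of 50 CPM or more, a choice that can lower them.

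Fyn was lower in the Fyn-KO libraries but still counted in them. A low share of glial RNA could lower its count without any change in the gene, and it is left open by the test, in which Fyn kept a larger share of its WT level than the median oligodendrocyte progenitor-like gene in 3 of the 4 libraries. Fyn kept 9.39, 9.42, 6.65 and 16.9%, where those genes kept 0.802, 0.725, 11.7 and 3.66%. Fyn made by other cells could leave such a remainder, and so could 3' tags of an altered transcript, and neither was tested.

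The WT libraries held fewer genes than the Fyn-KO libraries. Lower depth may be set aside, because after thinning to 8976745 counts each the difference was 5152 genes. A few genes taking most of the counts may be set aside as well, since the 10 most abundant genes took at most 8.27% in a WT library. Few starting RNA molecules in WT remain a candidate explanation: of genes at 100 CPM or more in 1 WT library, 17.6% (95% exact interval 17.0 to 18.2%) lay under 1 CPM in another WT library, against 0.00428% among the Fyn-KO libraries. The interval treats gene pairs as independent although the same genes and libraries recur, and it does not cover the spread between libraries. Differences between tumours in cell content could give such a share of missed genes too.

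Of 151 measures, 26 had 1 Fyn-KO library far from the other 3 by Dixon's gap over range, where chance gives about 1 in 20 measures, and the WT libraries were too few for this screen. In Fyn-KO replicate 3 the 10 most abundant genes took 23.1% of counts (others 16.8 to 17.4%), Rn45s 16.6% (10.5 to 10.98%) and Malat1 2.03% (2.35 to 2.41%), and the TMM factor was 0.940 (1.04 to 1.05). Its list levels stood apart for Fyn substrates and partners (4.97, others 4.78 to 4.80), complement (4.47, others 4.93 to 4.95), hypoxia response (4.65, others 4.94 to 4.95), nuclear-encoded oxidative phosphorylation (7.39, others 7.63 to 7.64), cholesterol synthesis (6.90, others 7.16 to 7.204) and the neural progenitor-like state (4.48, others 3.24 to 3.44). Its CPM stood apart for Acan (1.42, others 0), Tmem163 (2.74, others 0 to 0.111), Pdgfra (134, others 69.2 to 74.0), Cnp (239, others 28.7 to 64.4), Etv5 (29.6, others 8.58 to 10.1), Hmgcs1 (1959, others 2899 to 3018), Cyp11a1 (13175, others 11509.5 to 11689) and Hsd3b1 (4119, others 7112 to 7552). In Fyn-KO replicate 4 the type I interferon level was 3.22 (others 3.66 to 3.71), the level of glioma receptor tyrosine kinases and ligands 4.30 (others 3.94 to 3.96), and Mmp12 stood at 2.01 CPM (others 0). In Fyn-KO replicate 1 the sex-linked level was 3.75 (others 3.03 to 3.08), Blk stood at 2.66 CPM and Scgb1a1 at 0.107 CPM (others 0 for both), and Lfng at 17.6 CPM (others 6.25 to 7.35). In Fyn-KO replicate 2 Lck stood at 7.12 CPM (others 0 to 0.109).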

How the results depend on the processing

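The count of higher genes, 2493, was between 1968 and 2546 with RLE factors, library sizes alone, no filter, a minimum count of 50, robust edgeR, without Rn45s and after thinning. It was 3699 by DESeq2, 24 by limma-voom with quality weights, 188 with a block for the replicate number and 52 among genes detected in both groups, where fewer genes were tested. With 1 library left out it ranged from 2190 to 4585. The count of lower genes, 461, was 404 to 475 in the first group of alternatives, 774 by DESeq2, 320 by limma-voom with quality weights, 135 with the block, 146 among genes detected in both groups, 724 at an adjusted p under 0.1 and 247 to 839 with 1 library left out. Deviations from the group means hardly correlated between libraries with the same replicate number (-0.0142, -0.000155 and -0.0205). These numbers follow the columns and may not match the mice, so a true pairing was not tested. The number of lists called, 12, was 0 with an estimated correlation and 27 by fry, and 12 to 16 with 1 library left out. The first principal component held 50.9% over all tested genes, against 78.2%. Except where more or fewer genes or libraries were used, the cause was not tested.

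The log2 fold change of Fyn lay between -2.78 and -3.77 and passed the threshold in each alternative run. Of 83 other named genes, the direction and side of the threshold were the same for each under RLE factors, robust edgeR, no filter and without Rn45s, for 79 by DESeq2, 40 by limma-voom and 49 with the block. The direction reversed for Lyn (-0.35 without WT replicate 1, in a range of -0.35 to 0.70 with 1 library left out), and the cause was not tested. Sex was not fitted as a covariate, since Xist read 0.855 CPM in WT replicate 2 and Y-linked genes had few or no counts in any library. Simulated changes of 4-fold were recovered in 0 of 66 genes, but the smallest absolute log2 fold change called in the data was 0.77, so that the simulation sets no limit on what could be called.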

Other observations

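The lists in this part were chosen after the steroidogenic genes had been seen, and so was the test of the splits for the lists, whereas that of the splits for the gene counts was planned. The ovarian, adrenal, Leydig, lung and liver lists were written after the values of their own genes had been looked at. Their counts describe these data and are not independent support.

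Ovarian and germ cell genes were present in the Fyn-KO libraries. Of 18 tested genes of ovarian granulosa and luteal cells, 15 rose, against 16 when adjusted over the list alone, with a median log2 fold change of 10.71, or 8.01 with genes at 0 in WT at their bound. Foxl2, a transcription factor of granulosa cells, stood at 165 ± 55 CPM in Fyn-KO (ratio 6835, 95% counting interval 1226 to 270003), and Lhcgr, the luteinising hormone receptor, at 131 ± 16.9 CPM, at least 520.4-fold higher. Of 5 tested oocyte genes, 5 rose (median 8.80, or 4.31 at the bound), among them Gdf9 (15.6 ± 4.89 CPM, at least 62-fold higher), Bmp15 (4.29 ± 2.46 CPM, at least 17-fold higher) and Zp3 (9.15 ± 7.51 CPM, at least 36-fold higher). Of 8 adrenal cortex genes 4 were tested, and these rose (median 13.75, or 9.25 at the bound), among them Cyp11b1, an enzyme of corticosteroid synthesis, at least 336-fold higher. Nr5a1, a regulator of steroid-producing cells of ovary and adrenal, was at least 479-fold higher. Of 12 tested Hox genes of paralog groups 5 to 13, 11 rose, against 12 when adjusted over the list alone (median 9.66, or 6.51 at the bound). Oocyte, adrenal cortex and Leydig genes had no count in WT, and the Hox genes together stood at 0.359 CPM there. Members of these lists could pass the filter only through Fyn-KO, so a tested member could only be higher. The counts over all members, given below, do not depend on the filter. Testis Leydig genes counted 1 higher of 1 tested, Sertoli genes none of 1, adrenal medulla genes none of 2 (1 without Fyn-KO replicate 2), and no placental gene was tested. Apart from Hsd17b7, which is on the lists of steroid and of cholesterol synthesis, none of these genes is on another list. In Fyn-KO 16 of 18 ovarian, 5 of 10 oocyte, 3 of 8 adrenal cortex and 10 of 25 Hox genes reached 1 CPM in each library, against 0 of each in WT.

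In each WT library 4 of 12 lung epithelium genes and 1 of 10 liver genes reached 1 CPM, against 1 and 1 in each Fyn-KO library. Of 7 tested lung epithelium genes, 3 fell and 4 did not pass (median -4.39), with 6 that fell without WT replicate 2 and 2 without WT replicate 3 or Fyn-KO replicate 2, 3 or 4. The list's level was 3.34, 1.89 and 4.46 in WT and 0.46, 0.97, 0.57 and 0.84 in Fyn-KO. Of 3 tested liver genes, 1 fell, which was Alb at 332 ± 81.8 CPM in WT, with a median of 4.34 and a mean of -2.08, and without WT replicate 3, 1 rose. The source of the lung and liver transcripts in WT was not tested, so the content of the WT libraries is left open too.

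For the gene counts the real split gave 2954 genes, the highest other gave 0, and 1 of the 35 splits gave as many. That share is the smallest that 35 splits allow. Each other split put WT and Fyn-KO libraries in the same group, so this result does not tell genotype from other differences between the groups. For the lists called by camera a grouping by chance was not excluded: the real split gave 12 lists, 16 of the 35 splits gave as many or more, and the highest other gave 15.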
